A study of Mus musculus with 14 samples.

How the data were processed

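Whole uteri of mice at day 3.5 of gestation were profiled on 14 one-colour Affymetrix arrays, 1 per sample. The females were C57BL/6 wild type or homozygous for a mutation of Folr4, the gene now named Izumo1r, and had been given saline or folinic acid, a reduced folate, before mating. Per the labels, folinic acid was given as 2 intraperitoneal injections of 12.5 mg/kg, 10 and 3 days before mating. The groups were wild type with saline (n = 4), wild type with folinic acid (n = 3), mutant with saline (n = 3) and mutant with folinic acid (n = 4). The labels call the replicates biological, so each array was taken as a separate sample. The sample titles carry codes whose meaning is not stated. A number is shared by 2 wild-type saline samples and another by 2 wild-type folinic acid samples, so it is not known whether these are related, and n counts arrays.

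The deposited values are linear intensity signals, 1 per probe set, made by the authors from biotin-labelled target of the one-cycle assay. The submitters' processing notes name MAS5, without a version. All values were above 0, from 0.0624 to 95130, and the mean after trimming 2% at each end lay between 500.002 and 500.003 on every array, so each array had been scaled by 1 factor. No further normalization was applied. Detection calls and raw images were not used here. For arrays, their number limits the precision.

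The table held 45101 probe sets, of which 64 controls were left out. Of the other 45037, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none, and 34741 of those with 1 symbol were matched to the reference annotation by their gene identifier. Signals below 1 were raised to 1, which touched 0.505% of values, and all were put on the log2 scale. Probe sets were kept when their mean log2 signal over the 14 arrays was at or above the median of all non-control probe sets, a signal of 134. This left 22519 probe sets, 19116 with 1 symbol, for 11269 genes.

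Differences were tested with limma 3.58.1 in R 4.3.3. A fit with 4 group means gave 10 residual degrees of freedom, and the variances were moderated with a trend on mean signal, with 5.04 prior degrees of freedom. The 4 pairwise comparisons and the interaction of genotype and folinic acid were taken as contrasts of that fit. The tests were two-sided, p was adjusted by the Benjamini-Hochberg method within each comparison over all probe sets kept, and the threshold was an adjusted p of 0.05. Errors of log2 fold changes are standard errors of the fit. Folr4 itself was tested by an exact permutation test, two-sided, of the 7 wild-type against the 7 mutant arrays. The responses were also compared across genes by Pearson and Spearman correlations of log2 fold changes, set against 100 draws of permuted labels.

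Gene lists, 31 in all with 777 members, were fixed together with the groups, tests and alternatives before the data were examined. They cover folate and methyl-group metabolism, hormone response, implantation, decidualization, the cell types that a uterus at this stage can hold, immunity, proliferation, transport, tissue handling, the clock, oxidative phosphorylation and the neighbours of Folr4. Of the members, 717 matched a probe set and 537 were measured above the filter, each through its probe set with the highest mean log2 signal. The 28 lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01, and p was adjusted over the lists within each comparison. The same test with a correlation estimated from the arrays and limma's fry were run beside it. The fry test called 0 lists in every comparison for movement in 1 direction, and 1 list for mixed movement, after folinic acid in the mutants. Members were counted past the threshold over all genes and adjusted over the list alone.

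The genes named were chosen by a rule fixed in advance. In each comparison these were up to 12 genes per direction past the threshold, filled up to 5 per direction by the smallest p when fewer passed, up to 3 members of each list with the smallest p, and Folr4, Folr1 and Folr2. Genes added because of their values are named as such.

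The other settings tried were quantile normalization, an offset of 16 added before the logarithm, no filter, a filter at the upper 35 percent, 1 probe set per gene, variances without a trend, robust variances, array weights, a fit on the groups compared only, a replicate block, and leaving out each array in turn. Leaving out 2 arrays together, averaging the genotype effect over injections and the folinic acid effect over genotypes, and a covariate for RNA quality were added after the data had been seen, the last with its possible outcomes written down before it was run. RNA quality was read from the 3-prime to 5-prime signal ratios of the actin and Gapdh control probe sets.

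The procedure was tested on simulated data of the same size, with noise drawn independently for each probe set and array. Of simulated 2-fold changes, 53.7% were recovered for folinic acid in wild type, 55.2% for folinic acid in mutants, 49.3% for genotype under saline, 56.7% for genotype under folinic acid and 14.9% for the interaction. Of 4-fold changes, 77.6% were recovered for the interaction and 91.0% to 95.5% for the pairwise comparisons. False calls numbered 7 to 17 per comparison, among 137 to 183 calls. Signals that vary together across probe sets, as they can on real arrays, were left out of the simulation. These shares and false calls therefore do not measure the error rates in the real data.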

Results

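Expression was measured in whole uterus at day 3.5 of gestation, before implantation, in 14 samples. The groups were wild type with saline (n = 4), wild type with folinic acid (n = 3), Folr4 mutant with saline (n = 3) and Folr4 mutant with folinic acid (n = 4). The series asks whether the genotype alters the uterine response to folate given before conception. The median signal per array lay between 130.0 and 157, and the mean Spearman correlation of an array with the others between 0.912 and 0.951. The actin 3-prime to 5-prime ratio, a sign of RNA quality, ranged from 1.54 to 3.64, highest in wild-type saline replicate 3, and the Gapdh ratio from 1.14 to 2.48.

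Folr4, which encodes the egg receptor for the sperm protein Izumo1 and is also expressed on regulatory T cells, gave a dim signal in this tissue. Its probe set averaged 39.4 ± 23.01 (SD, n = 7) in wild-type and 22.8 ± 24.2 (SD, n = 7) in mutant uteri. The ranges were 13.5 to 72.4 and 6.14 to 70.2. The difference was -1.12 on the log2 scale (exact permutation p = 0.0991 over 3432 relabellings). By group the signal was 47.7 ± 22.0 (SD, n = 4) in wild type with saline and 28.2 ± 23.1 (SD, n = 3) in wild type with folinic acid. It was 29.5 ± 35.3 (SD, n = 3) in mutants with saline and 17.7 ± 16.2 (SD, n = 4) in mutants with folinic acid. Of these means, 3 rest on 1 high array: wild-type folinic acid replicate 3 (54.8; the others 13.5 and 16.3), mutant saline replicate 2 (70.2; the others at or below 11.4) and mutant folinic acid replicate 3 (41.3; the others 6.14 to 14.8). At percentile 23.04 of mean signal it lay below the filter, so it could not serve as a check of the genotype labels. Folr1, which takes up folate in epithelia, was below the filter as well. Its signal was 170.2 ± 103 (SD, n = 4) in wild type with saline, where replicate 3 had 322 and the others 98.1 to 143, and 106 ± 15.3 (SD, n = 3) in wild type with folinic acid. It was 93.8 ± 30.1 (SD, n = 3) in mutants with saline and 91.2 ± 28.3 (SD, n = 4) in mutants with folinic acid. Folr2, a folate receptor of macrophages, was measured. Its log2 differences were -0.12 ± 0.42 for folinic acid in wild type and 0.32 ± 0.42 in mutants. They were -0.54 ± 0.42 for genotype under saline, -0.09 ± 0.42 for genotype under folinic acid and 0.45 ± 0.59 for the interaction, none past the threshold.

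The comparison of genotypes under saline asks what the Folr4 mutation does without added folate. Erdr1, the erythroid differentiation regulator encoded at the end of the sex chromosomes, was 31.5-fold higher in mutant uteri (n = 3) than in wild-type uteri (n = 4). The log2 difference was 4.98 ± 0.35 and the adjusted p 8.36e-06. Its signal was 285 ± 119 (SD, n = 4) in wild type with saline and 8639 ± 3032 (SD, n = 3) in mutants with saline. No mutant array fell inside the wild-type range. Mid1, a microtubule-bound ubiquitin ligase whose gene neighbours Erdr1, had a log2 difference of 2.88 ± 0.74 that did not pass (adjusted p = 0.9998). Erdr1 was the 1 probe set of 22519 that passed in limma. At the same time 700 had an unadjusted p under 0.05, 293 higher and 407 lower, with 1126 expected by chance.

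**Figure D1:**
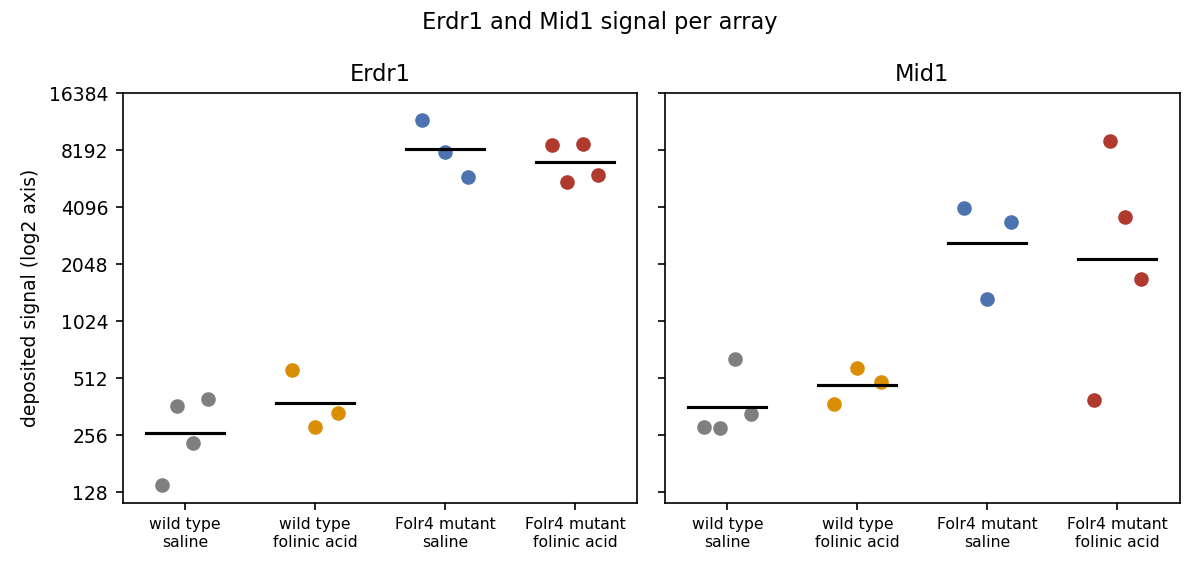
Deposited signal (log2 axis) of Erdr1 and Mid1 in each of the 14 uteri, by genotype and injection, with a bar at each group's mean on the log2 scale. The Erdr1 signal of the mutants lies between 5553 and 11929 and that of the wild type between 141 and 570, while 1 mutant array with folinic acid has a Mid1 signal of 395, inside the wild-type range.

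Among genes that did not pass under saline, those with the smallest p and higher values in mutants were the phosphatidylserine decarboxylase pseudogene Pisd-ps3 (1.01 ± 0.24), Wee1, the kinase that restrains mitotic entry (1.04 ± 0.27), and Etnk1, which phosphorylates ethanolamine (0.98 ± 0.26). Lower values were found for the ubiquitin ligase Rnf144b (-1.44 ± 0.33), Samhd1, which breaks down deoxynucleotides (-1.71 ± 0.40), Nnt, a mitochondrial transhydrogenase (-0.71 ± 0.17), Eif2a (-0.79 ± 0.19) and Mapk8ip1 (-0.68 ± 0.17), all with an adjusted p of 0.9998. Other probe sets of the genes named had the same sign in 13 of 16 cases. For Samhd1, 4 other probe sets gave smaller log2 differences of -0.30, -0.26, -0.36 and -0.11.

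Gene groups were also tested as lists, and camera called 8 for genotype under saline. Other splits of the same arrays called a median of 6.5 lists. For folinic acid in wild type camera called 2 against a median of 6, and in mutants 9 against 8. For genotype under folinic acid it called 10 against 9.5, and for the interaction 10 against 8 in draws of permuted labels. Chance therefore cannot be excluded for the number of lists called in any comparison. Progesterone-response genes of the uterus were higher in mutants, with 24 of 28 members on that side and a median log2 difference of 0.32, such as the activin antagonist Fst (1.55 ± 0.63). The adjusted p was 0.00183 by camera (adjusted p = 0.741 with an estimated correlation). The epithelial list was also higher, with a median of 0.18 over 23 members (17 positive; adjusted p = 0.0261; adjusted p = 0.788 with an estimated correlation). It included the tight-junction gene Cldn3 at 0.93 ± 0.42. The list for ion and water transport of the uterine lumen had a median of 0.21 over 15 members (adjusted p = 0.0484; adjusted p = 0.707 with an estimated correlation). Oxidative phosphorylation had a median of 0.10 with 26 of 33 members higher (adjusted p = 0.00892; adjusted p = 0.767 with an estimated correlation). Of the immune lists, 4 were lower in mutants by camera with the preset correlation. Macrophage and dendritic cell genes had a median of -0.46 (16 of 18 members lower; adjusted p = 0.00491) and genes of neutrophils, eosinophils and mast cells -0.60 (9 of 9; adjusted p = 0.0261). MHC class II and antigen presentation genes had -0.41 (15 of 16; adjusted p = 0.00183) and cytokines and chemokines -0.33 (14 of 16; adjusted p = 0.0261). Each of these 4 had an adjusted p of 0.767 with an estimated correlation. Ccr2, the chemokine receptor of monocytes, was lower by -1.11 ± 0.29. It was the 1 macrophage gene that passed when adjusted over the list alone, against 0 over all genes. In the B cell list, which was not called, the antibody genes Igha (1.75 ± 0.55) and Jchain (1.71 ± 0.58) passed when adjusted over the list alone, 2 genes against 0 over all genes. The macrophage median moved to -0.13 without mutant saline replicate 1, the MHC class II median to -0.06 without wild-type saline replicate 4. The progesterone and oxidative phosphorylation medians moved to 0.11 and 0.04 without wild-type saline replicate 3. The epithelial median was 0.04 without wild-type saline replicate 1 and 0.33 without replicate 3 of that group, the neutrophil median -0.31 without mutant saline replicate 3 and the ion transport median 0.10 without wild-type saline replicate 2. Of the 8 camera calls, 7 ended without 1 array, all but that of the progesterone list. Without wild-type saline replicate 4 the calls of macrophages, neutrophils, MHC class II (adjusted p = 0.471), cytokines (median -0.25, adjusted p = 0.249), epithelium and ion transport ended. Without wild-type saline replicate 3 those of neutrophils, cytokines and oxidative phosphorylation (adjusted p = 0.289) ended, and without wild-type saline replicate 1 those of epithelium (adjusted p = 0.474) and ion transport. Among the mutant saline arrays, leaving out replicate 1 ended the calls of macrophages (adjusted p = 0.425), cytokines, epithelium and ion transport, and leaving out replicate 3 those of neutrophils (adjusted p = 0.226), epithelium and ion transport. In total 9 of the 14 arrays ended the ion transport call when left out (highest adjusted p = 0.249), mutant saline replicate 2 and replicates 1 and 3 of wild type and 3 and 4 of mutants with folinic acid among them. The number of probe sets at an unadjusted p under 0.05 became 1121 without wild-type saline replicate 2 and 468 without wild-type saline replicate 1.

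The comparison of genotypes under folinic acid asks whether mutants differ once folate has been given. Erdr1 was again higher in mutants (n = 4) than in wild type (n = 3), 18.8-fold, with a log2 difference of 4.24 ± 0.35 and an adjusted p of 7.88e-05. Its signal was 7307 ± 1742 (SD, n = 4) against 397 ± 152 (SD, n = 3). Pdgfd, a platelet-derived growth factor ligand, had the next smallest p, with a log2 difference of -2.67 ± 0.47 and an adjusted p of 0.524. Its signal was 132 ± 61.7 (SD, n = 4) against 829 ± 319 (SD, n = 3). Erdr1 was the 1 probe set that passed in limma, while 858 had an unadjusted p under 0.05, 341 higher and 517 lower. Without mutant folinic acid replicate 2 that number was 1681.

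Further genes with small p that did not pass were, on the higher side in mutants, Dnajc16 (0.85 ± 0.21), Smim14 (0.61 ± 0.16), the chromatin regulator Kmt2e (0.49 ± 0.13) and the amino acid transporter Slc38a2 (0.70 ± 0.19). On the lower side were the plasma-membrane calcium pump Atp2b2 (-1.38 ± 0.31), the epithelial cadherin Cdh16 (-2.07 ± 0.47), Tcf19 (-0.80 ± 0.18) and Fech, which inserts iron into haem (-0.66 ± 0.16). These 8 genes had an adjusted p of 0.999, and other probe sets of the genes named had the same sign in 10 of 10 cases.

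Cell cycle and proliferation genes were lower in mutants than in wild type under folinic acid, with 28 of 29 members on that side and a median of -0.60. The adjusted p was 2.01e-13 by camera (adjusted p = 0.549 with an estimated correlation). Examples were the thymidine kinase Tk1 (-1.22 ± 0.41), the spindle midzone gene Prc1 (-0.89 ± 0.32) and the cyclin Ccne2 (-0.70 ± 0.26). The list of folate uptake and one-carbon enzymes was lower as well, with 18 of 21 members and a median of -0.26 (adjusted p = 4.97e-04; adjusted p = 0.549 with an estimated correlation). Gcsh of the glycine cleavage system was at -0.35 ± 0.15 and the methionine synthase gene Mtr at -0.58 ± 0.28. Progesterone-response genes had a median of -0.34 with 20 of 28 lower (adjusted p = 0.0217), among them the retinoic acid hydroxylase Cyp26a1 (-1.52 ± 0.47). Adipocyte genes had a median of -1.05 with 9 of 9 lower (adjusted p = 0.00558), among them Scd1 (-1.10 ± 0.65). Without wild-type folinic acid replicate 3, Scd1 was at -0.56 and Mtr at -0.34, and Scd1 was at -1.73 without wild-type folinic acid replicate 2. The progesterone and adipocyte lists each had an adjusted p of 0.549 with an estimated correlation.

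Of the lists with higher values in mutants under folinic acid, the immediate-early and tissue-handling genes had the smallest p by camera. They had 23 of 24 members higher and a median of 0.35 (adjusted p = 1.92e-07; adjusted p = 0.191 with an estimated correlation). Among them were the transcription factors Atf3 (0.74 ± 0.28), Junb (0.66 ± 0.26) and Klf4 (0.55 ± 0.22). Smooth muscle genes had a median of 0.18 (20 of 23; adjusted p = 0.00199; adjusted p = 0.698 with an estimated correlation). B cell and plasma cell genes had 0.53 (7 of 7; adjusted p = 0.0180; adjusted p = 0.338 with an estimated correlation). Macrophage and dendritic cell genes had a median of 0.42 (18 of 18; adjusted p = 4.97e-04; adjusted p = 0.634 with an estimated correlation). The MHC class II list had 0.20 (15 of 16; adjusted p = 0.0258; adjusted p = 0.711 with an estimated correlation). The cytokine list had 0.31 (13 of 16; adjusted p = 0.0163; adjusted p = 0.549 with an estimated correlation). The haem synthesis gene Alas2 of the blood list, -0.84 ± 0.31, passed when adjusted over the list alone, 1 gene against 0 over all genes. The blood list was too short to test, so an adjustment over it alone is slight. The macrophage median became -0.0468 and the MHC class II median -0.0665 without mutant folinic acid replicate 1. The latter was -0.0517 without wild-type folinic acid replicate 1. Without mutant folinic acid replicate 1 the cytokine median was 0.14 and the immediate-early median 0.21. The smooth muscle median ranged from 0.07 without mutant folinic acid replicate 2 to 0.45 without wild-type folinic acid replicate 2, and the B cell median from 0.29 without wild-type folinic acid replicate 1 to 0.82 without replicate 2 of that group. The adipocyte median moved to -0.38 without wild-type folinic acid replicate 3 and the progesterone median to -0.09 without mutant folinic acid replicate 4. The cell cycle median moved to -0.37 without wild-type folinic acid replicate 3. Of the 10 camera calls, 7 ended without 1 array, all but those of the cell cycle, folate enzymes and immediate-early genes. Without mutant folinic acid replicate 1 the calls of macrophages (adjusted p = 0.918), MHC class II (adjusted p = 0.924), cytokines (adjusted p = 0.529), progesterone response and adipocytes ended. Leaving out replicate 2 of that group ended the call of smooth muscle (adjusted p = 0.346), replicate 3 those of B cells and MHC class II, and replicate 4 that of progesterone response (adjusted p = 0.387). Among the wild-type folinic acid arrays, leaving out replicate 1 ended the calls of B cells (adjusted p = 0.328), MHC class II, cytokines, smooth muscle and progesterone response. Leaving out replicate 2 ended those of MHC class II and progesterone response, and replicate 3 those of adipocytes (adjusted p = 0.374), cytokines and smooth muscle.

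Folinic acid in wild-type uteri, the response of a normal uterus to the supplement, gave no gene past the threshold between 3 treated and 4 saline samples. The genes with the smallest p and higher values after folinic acid were Wdr48, a partner of deubiquitinases (0.85 ± 0.18, 1.80-fold), the kinase Sik3 (0.86 ± 0.20) and the Fanconi anaemia pathway gene Faap20 (1.22 ± 0.30). They were followed by Tom1l2 (0.54 ± 0.13) and the flap endonuclease Fen1 (0.84 ± 0.22). Those with lower values were the RNA-binding protein gene Hnrnpu (-0.97 ± 0.20), Marcks, a substrate of protein kinase C (-1.02 ± 0.24), Tex261 (-1.13 ± 0.27), the actin-binding Tmsb10 (-0.56 ± 0.14) and the mRNA export gene Thoc1 (-0.92 ± 0.25). All had an adjusted p of 0.999995, and other probe sets of these genes had the same sign in 17 of 23 cases. Many of these moved little, such as those of Wdr48 (0.15 and 0.11), Sik3 (0.05 and -0.09) and Thoc1 (0.03 and -0.04). Those of Tex261 (0.007 and 0.16) had the opposite sign, and those of Hnrnpu were -0.12, -0.21, 0.25 and -0.006. Larger values were found for Tmsb10 (-0.56 and -0.42, with 0.14 in another) and 1 probe set of Marcks (-0.52). The limma test called 0 of 22519 probe sets. Of these 611 had an unadjusted p under 0.05, 268 higher and 343 lower, against 1126 expected.

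Genes of endometrial stroma and fibroblasts were lower after folinic acid in wild type, with a median of -0.19, 14 of 23 members lower and an adjusted p of 6.87e-06 by camera. This call also held with an estimated correlation (adjusted p = 0.0441). The members with the smallest p were the intermediate filament gene Vim (-0.45 ± 0.14), the collagen Col3a1 (-0.34 ± 0.12) and the proteoglycan Lum (-0.56 ± 0.22), which was at -0.36 without wild-type folinic acid replicate 3. After quantile normalization the stroma median was 0.0204 and the call was lost (adjusted p = 0.387), with Col3a1 at -0.03. Adipocyte genes were higher, with a median of 0.91 and 9 of 9 members on that side (adjusted p = 0.00705; adjusted p = 0.982 with an estimated correlation). Among them were the adipokine Retn (1.96 ± 1.22), the desaturase Scd1 (0.91 ± 0.65) and the lipase Lipe (0.31 ± 0.24). Retn was at 0.48 without wild-type saline replicate 2, and Scd1 at 0.37 without wild-type folinic acid replicate 3 and 1.54 without wild-type folinic acid replicate 2. The adipocyte median ranged from 0.23 without wild-type saline replicate 2 to 1.51 without wild-type folinic acid replicate 2. The adipocyte call ended without wild-type saline replicate 2 (adjusted p = 0.385), wild-type saline replicate 4 (adjusted p = 0.0814) or wild-type folinic acid replicate 3 (median 0.37, adjusted p = 0.559). The stroma median reached -0.10 without wild-type folinic acid replicate 3. Among the neighbours of Folr4, Smco4 (0.59 ± 0.17) passed when adjusted over the list alone, 1 gene against 0 over all genes.

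Folinic acid in mutant uteri gave no gene past the threshold between 4 treated and 3 saline samples. Higher values after folinic acid were found for Fgfrl1, a receptor of the fibroblast growth factor family without a kinase domain (0.99 ± 0.18, 1.99-fold) and Sting1, the adaptor of cytosolic DNA sensing (1.26 ± 0.24, 2.40-fold). The next were Mylip, which directs the LDL receptor to degradation (0.98 ± 0.20), the O-GlcNAc transferase Ogt (1.12 ± 0.23) and the sphingomyelin synthase Sgms1 (1.06 ± 0.22). Lower values were found for the mRNA export adaptor Alyref (-1.05 ± 0.17), the mitochondrial alanine aminotransferase Gpt2 (-1.44 ± 0.25), Carhsp1 (-1.07 ± 0.19), the chromatin reader Psip1 (-1.32 ± 0.24) and the fibrillar collagen Col3a1 (-0.63 ± 0.12). The adjusted p was 0.123 for Sgms1 and 0.120 for the other 9 genes. Other probe sets of these genes had the same sign in 12 of 15 cases, the exceptions being 1 each of Ogt, Sgms1 and Col3a1 (0.02). After quantile normalization Col3a1 itself was at 0.0188 (adjusted p = 0.960). The limma test called 0 probe sets, while 2887 had an unadjusted p under 0.05, 1367 higher and 1520 lower, against 1126 expected. With array weights 103 passed, 17 higher and 86 lower. Without mutant folinic acid replicate 2, 662 probe sets passed, 248 higher and 414 lower, and 4387 had an unadjusted p under 0.05.

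Cell cycle and proliferation genes were lower after folinic acid in mutants, with 28 of 29 members on that side and a median of -0.63. The adjusted p was 8.29e-08 by camera (adjusted p = 0.482 with an estimated correlation). The cyclin Ccne2 (-1.09 ± 0.26) and the ubiquitin-conjugating enzyme Ube2c of mitotic exit (-1.41 ± 0.40) passed when adjusted over the list alone, 2 genes against 0 over all genes. Progesterone-response genes had 22 of 28 members lower and a median of -0.59 (adjusted p = 2.18e-04; adjusted p = 0.355 with an estimated correlation). Examples were the endocytic receptor Lrp2 at -3.37 ± 0.99, the retinol transporter Stra6 at -0.67 ± 0.21 and the hedgehog ligand Ihh at -1.61 ± 0.56. Folate uptake and one-carbon enzymes had 17 of 21 members lower and a median of -0.23 (adjusted p = 0.00428; adjusted p = 0.482 with an estimated correlation). The proton-coupled folate transporter gene Slc46a1 was at -0.76 ± 0.25, Mthfd1l at -0.55 ± 0.19 and Gcsh at -0.43 ± 0.15, or -0.29 without mutant saline replicate 1. Oxidative phosphorylation genes had 31 of 33 members lower and a median of -0.26 (adjusted p = 2.99e-06; adjusted p = 0.340 with an estimated correlation). Cox7a2 was at -0.40 ± 0.12 and Cox5b at -0.35 ± 0.10. Stroma genes had a median of -0.14 with 17 of 23 lower (adjusted p = 0.00353; adjusted p = 0.340 with an estimated correlation). Of them 4 passed when adjusted over the list alone against 0 over all genes, among them Col3a1, Vim (-0.49 ± 0.14) and Igfbp4 (-0.44 ± 0.14). The stroma median was 0.0188 after quantile normalization (adjusted p = 0.642), with Igfbp4 at -0.10, and -0.0879 without mutant saline replicate 3 (adjusted p = 0.0518), the call ending in both, against -0.30 without mutant saline replicate 1. The cell cycle median was -0.26 without mutant saline replicate 3 and -0.99 without mutant saline replicate 2.

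Of the immune lists, 3 were higher after folinic acid in mutants by camera with the preset correlation. Macrophage and dendritic cell genes had a median of 0.71 with 17 of 18 members higher (adjusted p = 7.64e-05; adjusted p = 0.501 with an estimated correlation). Ccr2, at 1.32 ± 0.29, passed when adjusted over the list alone, 1 gene against 0 over all genes. MHC class II and antigen presentation genes had a median of 0.64 with 16 of 16 higher (adjusted p = 0.00105; adjusted p = 0.551 with an estimated correlation), such as H2-Eb1 (1.09 ± 0.50). Cytokines and chemokines had a median of 0.50 with 16 of 16 higher (adjusted p = 0.00149; adjusted p = 0.482 with an estimated correlation), such as Ccl5 (1.77 ± 0.63) and Il1b (1.88 ± 0.73). Immediate-early and tissue-handling genes, which respond within minutes to stress and dissection, had a median of 0.43 with 18 of 24 higher (adjusted p = 0.00114; adjusted p = 0.371 with an estimated correlation). Klf6 (0.63 ± 0.17) passed when adjusted over the list alone, 1 gene against 0 over all genes. The macrophage median ranged from 0.14 without mutant folinic acid replicate 1 to 1.06 without mutant folinic acid replicate 2. With the same arrays left out, the MHC class II median ranged from 0.33 to 0.96 and the cytokine median from 0.30 to 0.67. Without mutant folinic acid replicate 1 the calls of macrophages (adjusted p = 0.0662) and MHC class II (adjusted p = 0.0600) ended. In that case Ccl5 was at 1.15, Il1b at 1.01 and H2-Eb1 at 0.62. The immediate-early median was 0.28 without mutant folinic acid replicate 1. The share of the total signal held by the brightest 1% of probe sets was 33.8 ± 1.19 percent (SD, n = 3) in mutants with saline and 27.4 ± 1.35 percent (SD, n = 4) in mutants with folinic acid. The difference was -6.32 (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.343 over 12 comparisons).

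Members of lists that were not called, or were too short to test, also passed when adjusted over the list alone after folinic acid in mutants, against 0 over all genes. These were the maintenance methyltransferase Dnmt1 (-0.57 ± 0.16) and Mbd3 (-0.67 ± 0.19) and the phospholipase Pla2g4a of prostaglandin synthesis (-1.20 ± 0.30). Others were the calcium-binding gland gene Calb1 (-2.33 ± 0.63), the interferon-stimulated gene Xaf1 (-0.87 ± 0.20), and Atp1b1 (-1.63 ± 0.46), Sgk1 (-0.90 ± 0.28) and Fxyd4 (-1.91 ± 0.64) of the ion transport list. The B cell genes Blk (2.44 ± 0.65) and Ighm (1.62 ± 0.56) and Eomes (0.92 ± 0.30), counted with the embryo list and also a gene of NK cells, were higher. Eomes was at 0.59 without mutant folinic acid replicate 4. The embryo list was too short to test, so an adjustment over it alone is slight.

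**Figure D2:**
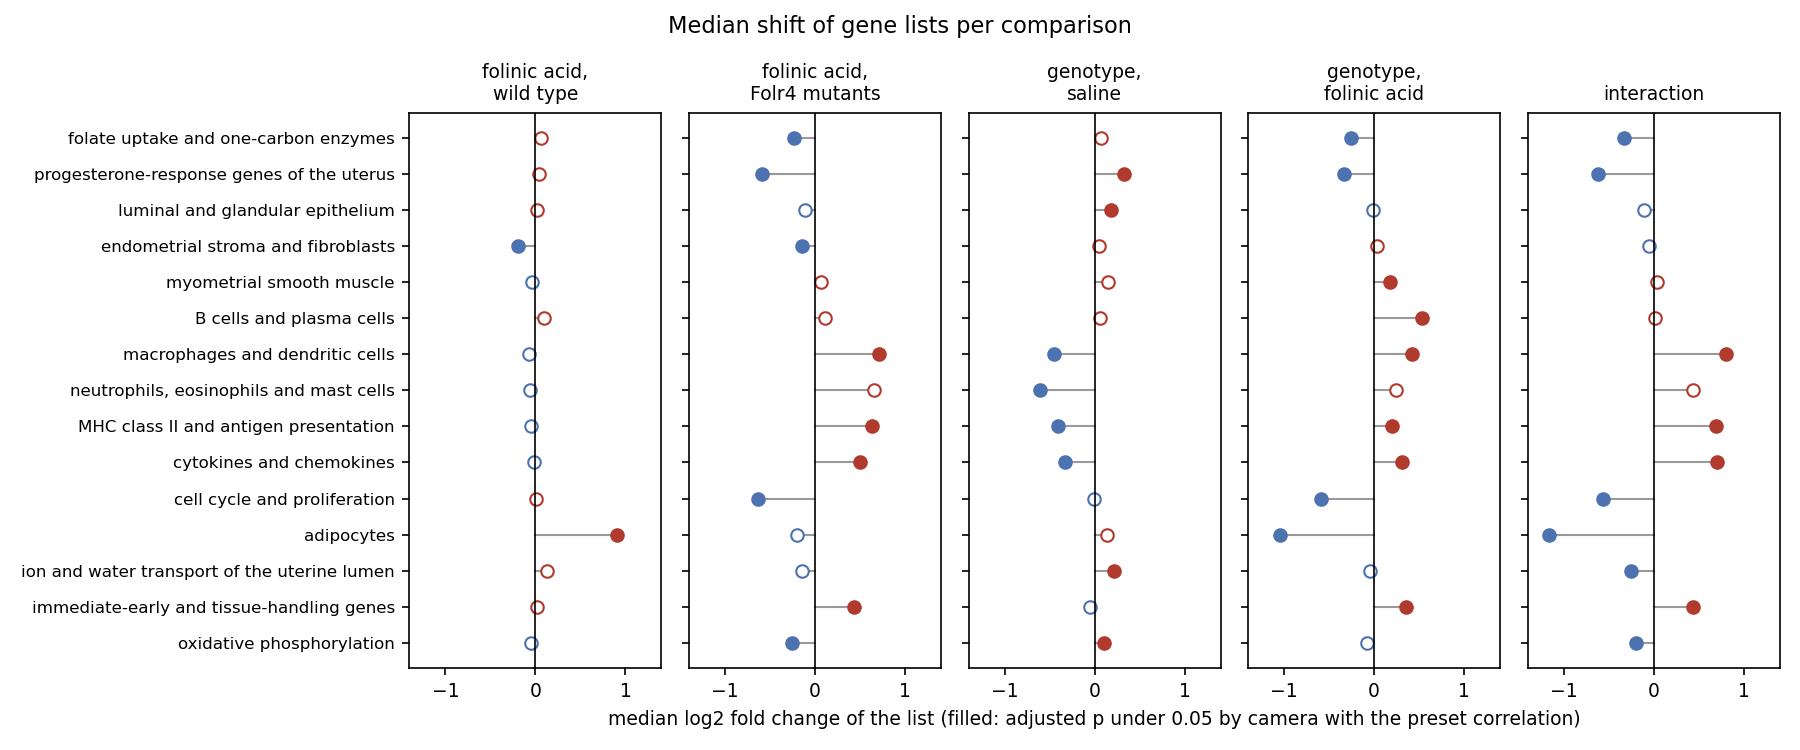
Median log2 fold change of the 15 gene lists called at least 1 time, in each of the 5 comparisons; filled points have an adjusted p under 0.05 by camera with the preset correlation. The macrophage list has a median of 0.71 after folinic acid in mutants and -0.46 for genotype under saline, and the cell cycle list -0.63 after folinic acid in mutants.

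The interaction asks directly whether the response to folinic acid differed between genotypes, which is the question of the series. No single gene passed. Genes with a response further up in mutants were the transcription factor Cux1 (1.39 ± 0.32), Fam124a (1.09 ± 0.26), the kinase Stk17b (1.35 ± 0.37), Zmiz1 (0.85 ± 0.23) and Rfx3 (1.39 ± 0.38). Those further down were the phosphatase Dusp14 (-1.38 ± 0.30), Gpt2 (-1.58 ± 0.35), Etnk1 (-1.66 ± 0.37), Atp2b2 (-1.93 ± 0.44) and Wee1 (-1.68 ± 0.39). All had an adjusted p of 0.905. Other probe sets of these genes had the same sign in 16 of 17 cases. The limma test called 0 probe sets, and 1104 had an unadjusted p under 0.05, 510 higher and 594 lower, against 1126 expected. Without mutant folinic acid replicate 2 that number was 2087.

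For the interaction, camera called 10 gene lists, against a median of 8 in draws of permuted labels. Further down in mutants were cell cycle and proliferation (median -0.57, 28 of 29 members; adjusted p = 5.32e-07), folate uptake and one-carbon enzymes (-0.33, 17 of 21; adjusted p = 0.00155), and oxidative phosphorylation (-0.20, 27 of 33; adjusted p = 0.00161). Further up were macrophages and dendritic cells (0.81, 17 of 18; adjusted p = 2.99e-05) and cytokines and chemokines (0.71, 13 of 16; adjusted p = 0.00161). These 5 lists had an adjusted p of 0.542 with an estimated correlation. Progesterone-response genes (-0.62, 23 of 28; adjusted p = 3.00e-04), ion and water transport (-0.26, 10 of 15; adjusted p = 0.0292) and, on the higher side, immediate-early genes (0.43, 19 of 24; adjusted p = 3.50e-04) each had an adjusted p of 0.369 with an estimated correlation. Adipocyte genes (-1.16, 9 of 9; adjusted p = 0.0252) had an adjusted p of 0.578 with an estimated correlation. MHC class II genes (0.69, 15 of 16; adjusted p = 3.00e-04) had an adjusted p of 0.548 with an estimated correlation. Examples were Mthfd2, the mitochondrial folate enzyme (-2.15 ± 0.86), Lrp2 (-3.97 ± 1.39), Ccr2 (1.34 ± 0.41) and Sgk1 (-1.36 ± 0.40). The macrophage interaction ranged from 0.34 without mutant folinic acid replicate 1 to 1.19 without mutant folinic acid replicate 2. The adipocyte median reached -0.25 without wild-type saline replicate 2, the MHC class II median 0.28 without wild-type saline replicate 4 and the cell cycle median -0.29 without mutant saline replicate 3, against -0.98 without mutant saline replicate 2. The median of the folate enzymes was -0.16 without wild-type saline replicate 3. Of the 10 calls, 2 ended without 1 array. That of adipocytes ended without wild-type saline replicate 2 or 4, wild-type folinic acid replicate 3, mutant saline replicate 3 (adjusted p = 0.395) or mutant folinic acid replicate 1. That of ion transport ended without wild-type saline replicate 1 or 4 or wild-type folinic acid replicate 3 (adjusted p = 0.0902). The mutant saline samples enter the folinic acid response of the mutants, the genotype comparison under saline and the interaction, so list shifts of opposite sign in these comparisons are not independent. The mutant folinic acid samples likewise enter the folinic acid response of the mutants, the genotype comparison under folinic acid and the interaction. List shifts of the same sign in those comparisons are therefore not independent either.

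Across 22519 probe sets, which are not independent replicates, the folinic acid responses of wild type and mutants had a Pearson correlation of 0.0989 (Spearman 0.121; permutation p = 0.62 over 100 draws). The genotype effects under saline and under folinic acid had a Pearson correlation of -0.252 (Spearman -0.221; permutation p = 0.37 over 100 draws). Without wild-type saline replicate 2 the correlation of the responses was -0.0767, and the correlation of the genotype effects was -0.114 without mutant folinic acid replicate 1.

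Of the 28 lists tested, 13 were called in no comparison, with a lowest adjusted p of 0.0548 for the oestrogen-response genes after folinic acid in mutants (median 0.37). The T cell list, in the same comparison, had a median of 1.44 over 7 members (adjusted p = 0.0662). Il7r was at 1.75 ± 0.63 and Lat at 1.48 ± 0.57. The lowest adjusted p of the others was 0.0553 for uterine gland genes (-0.31), 0.0622 for the methionine cycle (-0.16) and 0.0720 for NK cells (0.22), all for genotype under folinic acid. For the interaction it was 0.0681 both for interferon-stimulated genes (0.21) and for extracellular matrix remodelling (0.18). For genotype under saline it was 0.132 for the circadian clock (0.24), 0.293 for implantation and receptivity (0.03) and 0.685 for endothelium, whose median of -0.0013 and mean of 0.02 differ in sign. DNA and histone methylation reached 0.247 after folinic acid in mutants (-0.08), and decidualization (0.08) and the neighbours of Folr4 (-0.13) 0.537 for genotype under folinic acid. The lists for blood cells (3 measured genes), ovary and oviduct (4) and embryo (2) were too short to test, and their median log2 differences after folinic acid in mutants were -0.26, -0.08 and 0.57.

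**Figure D3:**
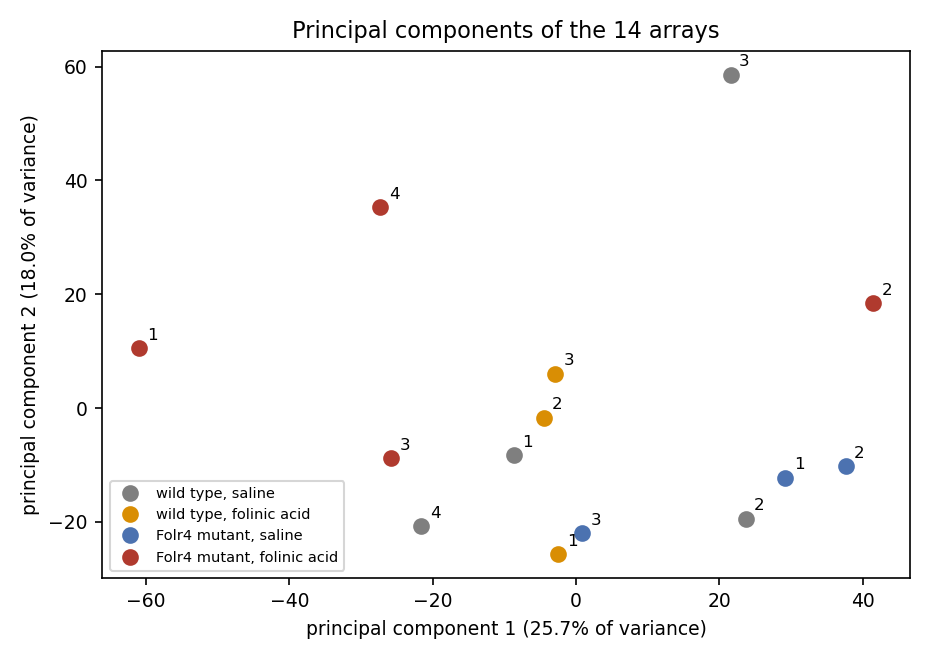
First and second principal components of the log2 signals of the 14 uteri (25.7% and 18.01% of the variance), coloured by group and numbered by replicate. Mutant folinic acid replicate 1 lies at -61.0 and replicate 2 of that group at 41.4 on the first component.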

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

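Of the tests below, those of Erdr1, of the genes around Folr4, of mutant folinic acid replicate 2, of the scaling, of single arrays and with a covariate for RNA quality were chosen only after the results they examine were seen; the quantile normalization and the leaving out of single arrays had been planned as such, and the possible outcomes of the covariate were written down before it was run.

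Erdr1 was higher in all 7 mutant uteri, and its lowest mutant signal was 9.75 times its highest wild-type signal. A wrong genotype label could blur such a gap but not make it. Since Erdr1 was picked because it differed between the labelled genotypes, the gap is no independent check of these labels. It says nothing of the injection labels. A second Erdr1 probe set differed by 2.23 on the log2 scale in the same direction (2.82 to 39.3 in wild type, 52.3 to 125 in mutants; exact permutation p = 5.83e-04, the smallest that 3432 relabellings can give), but it lies below the filter, so a fault of 1 probe set stays open. Since 0 mutant arrays fell inside the wild-type range, an effect of the mutation and a variant from another strain cannot be told apart, although such a variant would have to be fixed among the mutants, since Erdr1 does not share a chromosome with Folr4, and the labels give no strain history. Of 85 measured genes around Folr4, 5 had an unadjusted p under 0.05 for genotype averaged over injections, as many as in 1.66% of windows of equal size, but without Casp4, Pdgfd and Yap1, the genes that prompted the question, 3 of 82 did, as many as in 20.1% of windows of equal size, and that version was chosen after the first result. Donor-strain DNA linked to the mutated locus therefore stays open as a candidate explanation for Casp4 (-1.18; 146 to 592 in mutants, 661 to 1125 in wild type), Pdgfd (-1.71; 91.4 to 790 and 359 to 1167, with 2 mutant arrays inside the wild-type range) and Yap1 (-0.65, but 0.11 in a brighter probe set with 5 mutant arrays inside that range), all 3 with an adjusted p of 0.811 at the first value.

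Mutant folinic acid replicate 2 stood apart from its group: its mean distance to the mutant saline arrays was 0.505 and to its own group 0.664, a difference of -0.159, where 9 of the 14 arrays lay nearer another group than their own and the lowest such difference of the others was -0.0875. It also lay nearer the wild-type folinic acid arrays (0.536) and the wild-type saline arrays (0.554) than its own group. The distances therefore do not single out a wrong injection label. Such a label on this sample could give these values, as could a female that responded less to folinic acid. By distance, 0 of the 3 mutant saline arrays lay nearer the mutant folinic acid arrays than their own group. Yet the split that exchanged this array with mutant saline replicate 3 called 307 probe sets, with 4984 at an unadjusted p under 0.05. A swap with that array stays open. RNA quality cannot be told apart from a wrong label or a weaker response. The actin 3-prime to 5-prime ratio of 2.19 lay inside the group's range, while the Gapdh ratio of 2.05 (1.31 to 1.97 in the other 3 arrays) and the 18S control signal of 2661 (639 to 944) lay above it. Without this array, 662 probe sets passed after folinic acid in mutants, among them lower signals of Calb1 (-3.00), Lrp2 (-4.53), the pyruvate carboxylase gene Pcx (-2.29) and Galm (-2.62) and higher signals of Ogt (1.31) and Sting1 (1.43), genes picked here from the smallest p. With all arrays 0 passed in limma and 2887 had an unadjusted p under 0.05, and leaving the array out because of its values would favour such calls.

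The lists that shifted after folinic acid in mutants differ in what could account for them. For the stroma list, the median of -0.14 became 0.0188 after quantile normalization (adjusted p = 0.642). That step equalizes the bright end of the arrays, where this list lies (mean log2 signal 12.99 in mutants with saline). It could also remove a real fall of bright genes, so it cannot decide whether the authors' scaling of each array by 1 factor is the cause. The stroma median was -0.26 with the actin ratio as a covariate. Its median of -0.0879 without mutant saline replicate 3 (adjusted p = 0.0518) leaves open whether it rests on that array. The cell cycle median of -0.63 (adjusted p = 0.482 with an estimated correlation) was -0.66 after quantile normalization and -0.57 with the covariate. These values argue against the scaling and the actin ratio as the whole cause. The covariate was the actin ratio alone, so RNA quality that this ratio does not track stays open. Without mutant saline replicate 3 the cell cycle median was -0.26, still past the threshold of camera with the preset correlation. How far the cell cycle shift rests on that array therefore stays open. The macrophage median of 0.71 was 0.72 after quantile normalization and 0.41 with the covariate (adjusted p = 0.00900; adjusted p = 0.501 with an estimated correlation and no covariate), but its median of 0.14 without mutant folinic acid replicate 1 (adjusted p = 0.0662) shows that the preset-correlation call rests on that array. A biological difference in immune cells or proliferation between these animals stays open as an untested hypothesis, and chance cannot be excluded for the number of lists, since 15 of 35 splits of the 7 mutant arrays called at least the 9 lists of the real one, with 15 lists as the highest of the others.

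Single arrays lay far from the other 3 of their group in 11 of 160 groups of values, where 8 are expected by chance. In wild-type saline replicate 3 the mean log2 signal was 8.89 for the folate list (9.29 to 9.34 in the others), 9.90 for the methionine cycle list (10.30 to 10.33) and 12.27 for oxidative phosphorylation (12.50 to 12.52). In wild-type saline replicate 2 it was 10.03 for the oestrogen-response list (10.56 to 10.64) and 10.55 for decidualization (10.73 to 10.76), and in wild-type saline replicate 4 it was 12.35 for MHC class II (11.14 to 11.29). Mutant folinic acid replicate 2 had a log2 signal of 9.17 for Wee1 (8.12 to 8.28), 9.28 for Eif2a (9.72 to 9.78) and a mean of 10.45 for decidualization (10.75 to 10.81), besides the 18S signal of 2661. Mutant folinic acid replicate 1 had a mean of 10.49 for neutrophils, eosinophils and mast cells (8.87 to 8.97).

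The response to folinic acid differed between genotypes by camera for 10 lists, with median log2 interactions of -0.33 for folate enzymes, -0.62 for progesterone response, 0.81 for macrophages, 0.69 for MHC class II, 0.71 for cytokines, -0.57 for the cell cycle, -1.16 for adipocytes, -0.26 for ion transport, 0.43 for immediate-early genes and -0.20 for oxidative phosphorylation. None of them kept its call with an estimated correlation, where the lowest adjusted p was 0.369.

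Among the probe sets left out by the filter, which takes the mean over all arrays, 1 that carries no gene symbol was higher in mutants by 8.62 under saline (adjusted p = 9.65e-04) and by 8.31 under folinic acid (adjusted p = 0.00161), with signals of 0.756 to 30.8 in wild type and 1344 to 2469 in mutants. The ubiquitin ligase Neurl3 differed by -3.74 between genotypes under saline and by 3.78 after folinic acid in mutants, with signals of 66.5 to 159 in wild type and 6.30 to 277 in mutants. Boll, a germ-cell RNA-binding gene, differed by 3.00 after folinic acid in mutants, with signals of 82.9 to 149 in wild type and 9.48 to 171 in mutants. All 3 probe sets have signals near background in some arrays, so the sizes of these differences are not well determined.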

How the results depend on the processing

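Of the tests below, leaving out wild-type saline replicate 3 and mutant folinic acid replicate 1 together was chosen only after the data had been seen; the other alternatives were planned. Erdr1 passed the threshold for genotype under saline and under folinic acid in every alternative run. No alternative but array weights, no filter and leaving out mutant folinic acid replicate 2 called a probe set after folinic acid in mutants, and none called any after folinic acid in wild type or for the interaction. After quantile normalization the stroma median was 0.0204 for folinic acid in wild type and 0.0188 in mutants, and Col3a1 was 0.0188 in mutants; the alternative equalizes the bright end of the arrays, where this collagen lies. With no filter, 2 probe sets passed for folinic acid in mutants, 3 for genotype under saline and 2 for genotype under folinic acid, the additions being probe sets whose mean over all arrays lies below the filter, and the correlation of the genotype effects was -0.0210. Array weights called 103 for folinic acid in mutants, and a fit on the groups compared only called 2 for genotype under saline; the cause was not tested. Leaving out each array in turn gave 0 to 662 for folinic acid in mutants, 1 to 2 for genotype under saline, -0.0767 to 0.186 for the correlation of the folinic acid responses and -0.359 to -0.114 for that of the genotype effects, with the high counts without mutant folinic acid replicate 2; the cause was not tested here. For genotype under folinic acid the MHC class II median ranged from -0.0665 without mutant folinic acid replicate 1 to 0.51, with -0.0517 without wild-type folinic acid replicate 1, and the macrophage median from -0.0468 without mutant folinic acid replicate 1 to 0.76; the cause was not tested. Without the 2 arrays together, these medians were -0.0665 and -0.0468 and the correlations 0.224 and 0.0581; the cause was not tested. Of the list calls, recomputed under each alternative, 56 were lost (3 of them with a change of sign) and 490 kept when 1 array was left out, and 109 were lost (4 with a change of sign) and 357 kept under the others, camera with an estimated correlation and fry included. The 490 include arrays outside a pairwise comparison, whose loss cannot move its medians. Some single array ended the call of 1 list for folinic acid in wild type and 3 in mutants. It did so for 7 lists for genotype under saline, 7 under folinic acid and 2 for the interaction. Dim signals limit what can be said of Folr4 and Folr1, which lie below the filter.

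With the replicate number as a block, limma called 0 probe sets for folinic acid in wild type (648 at an unadjusted p under 0.05), 0 in mutants (2450), 1 for genotype under saline, 1 under folinic acid and 0 for the interaction (946), and camera called 3, 11, 7, 8 and 12 lists. The mean correlation of residuals was 0.0200 over 19 pairs of arrays with the same number and -0.00646 over 54 pairs with different numbers. It was over 0.1 in 6 of the 19 pairs and in 19 of the 54. Yet 8 of the 14 arrays had their highest correlation with an array of the same number. These values therefore do not decide whether the numbers pair some of the samples.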

Other observations

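Of the tests below, the averages over injections and genotypes and the splits for numbers of probe sets and for correlations were chosen only after the results were seen, while the splits for numbers of lists were set beforehand.

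Averaged over both genotypes, 1 probe set, which is shared by several predicted genes, was lower after folinic acid, with a log2 difference of -1.17 (adjusted p = 0.00917). Genes with a single symbol and the next smallest p, chosen after their values were seen and none past the threshold, were the mRNA export adaptor Alyref (-0.72), the collagen Col3a1 (-0.49), Sumf2 (-0.95), the ribosomal protein gene Rps10 (-0.49), Hnrnpu (-0.79) and, on the higher side, Faap20 (1.18), each with an adjusted p of 0.0999. Averaged over both injections, Erdr1 was 24.4-fold higher in mutants (adjusted p = 1.79e-07) and Mid1 5.82-fold higher without passing (adjusted p = 0.811).

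Other splits of the same arrays were counted for each comparison. For genotype under saline, 1 of 35 splits, the real one, called a probe set (1, with 0 as the highest of the others). That is the smallest share that 35 splits can give, in 1 of 15 counts of this kind. With allowance for these counts, 35 splits cannot exclude chance whatever the values. No conclusion on the limma call of Erdr1 is therefore drawn from them. For genotype under folinic acid, 3 of 35 splits called at least the 1 of the real split, with 7 as the highest of the others, so chance cannot be excluded for the count. All 35 splits gave at least the 0 calls of folinic acid in wild type (highest other 0), all 35 the 0 of folinic acid in mutants (highest other 917) and all 100 the 0 of the interaction (highest other 236). These shares were fixed in advance, since any count is at least 0, so they do not bear on whether a response exists. At an unadjusted p under 0.05, 23 of 35 splits gave at least the 611 probe sets of folinic acid in wild type (highest other 2481), 4 of 35 the 2887 of folinic acid in mutants (4984), 18 of 35 the 700 of genotype under saline (2717), 23 of 35 the 858 of genotype under folinic acid (2347) and 43 of 100 the 1104 of the interaction (4749), so chance cannot be excluded for any of these 5. Why some splits call 917 or 236 probe sets was not tested. The 917 came when mutant folinic acid replicate 2 was moved to the saline arrays, and the 4984 when it changed places with mutant saline replicate 3.

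For the number of lists called by camera, 34 of 35 splits gave at least the 2 of folinic acid in wild type (highest other 16), 15 of 35 the 9 of folinic acid in mutants (15), 9 of 35 the 8 of genotype under saline (12), 18 of 35 the 10 of genotype under folinic acid (16) and 34 of 100 the 10 of the interaction (17). Chance cannot be excluded for any of these numbers of lists. For the correlations across genes, 62 of 100 draws lay as far from 0 as the 0.0989 between the folinic acid responses (highest other 0.467) and 37 of 100 as far as the -0.252 between the genotype effects (highest other 0.489), so chance cannot be excluded for either.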
